A study of Rattus norvegicus with 46 samples.

How the data were processed

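RNA from the proximal gastrocnemius muscle of 23 female Sprague-Dawley rats was measured on 46 single-colour Affymetrix expression arrays, 1 array for each leg. Per the labels, the rats were anaesthetised with isoflurane, paralysed with α-cobrotoxin, a snake toxin that blocks the nicotinic acetylcholine receptor of the neuromuscular junction, and mechanically ventilated. The left ankle was moved passively by a lever at 13.3 cycles per minute, for 6 h at the shortest duration and otherwise for 12 h per day, and the other leg was left unloaded. The labels give 6 groups, loaded or unloaded legs studied for 6 h to 4 d, 5 to 8 d or 9 to 14 d. Exact durations were not used, so a window pools rats of different durations. No untreated rats were measured, so changes with duration are against rats paralysed for 6 h to 4 d.

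The deposited table holds 1 log2 expression value per probe set and array, for 26208 probe sets. Per the submitters' notes the authors made these values with RMA, robust multi-array averaging, of unstated version. It corrects background, quantile-normalises and summarises probes. Values ran from 1.92 to 14.38, and the medians of the arrays from 6.07 to 6.20. Quantile normalisation gives all arrays nearly the same distribution, so a change that shifts most transcripts in 1 direction would be partly removed, and no signal above background or detection call was used here. In comparisons of windows Emb, Dclk1, Ppp1r14c, Adra1b, Ostn, Mss51, Mstn, Aqp4, Fbp2, Kera, Postn, Mymk, Lgi2, Adgre1, Slc51a and Ctxn3 have a group mean below the lowest array median in at least 1 comparison. Signal over background is not shown there, so the size of these differences is uncertain and no fold is given. The number of arrays limits the precision. No control probe sets for RNA quality were among the values, so the planned comparison of their 3 prime and 5 prime ends was not made.

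Genes were named from the platform annotation paired with the table's probe sets. It lists 15411 of the probe sets, of which 15088 have 1 gene symbol (14317 genes) and 323 have several, and 10797 are without a listed gene. Symbols are those of the annotation and can be old. A probe set was kept if it exceeded its own array's median on at least 4 arrays, which left 14834 probe sets. The kept probe set with the highest mean stood for its gene, which gave 9289 genes. Rps19 and Rps20 each have several near-identical probe sets, so transcripts of related genes cannot be told apart there and their values are uncertain. Psmd8 and Tecr each have another kept probe set that is dimmer and was not used for the named value.

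Legs were paired by label number, as each odd-numbered unloaded leg is followed by a loaded leg of the same window and date code. A rat is named by the number of its unloaded leg. The labels do not state which legs belong together, so the 23 pairs are inferred. As a check, the deviations of both legs from their group means correlated above 0.1 across genes in 21 of 23 rats (median r = 0.60). The exceptions were rat 17 (r = 0.08) and rat 27 (r = -0.35). An unloaded leg correlated best with its own loaded leg in 15 rats, and the reverse held in 14. Neither held in rats 17, 19, 21, 23 and 27 (6 h to 4 d) and 51 (9 to 14 d). Their pairing is uncertain.

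Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the 9289 genes, threshold 0.05), and every adjusted p of a single gene below comes from it. Loaded and unloaded legs were compared in 1 fit over all 46 arrays with the rat as a block, within each window and over all 23 rats, and the loading effects of the windows were compared in the same fit. Windows were compared in the 23 unloaded legs and in the 23 loaded legs separately, with 1 array per rat. The effect of loading at 9 to 14 d was set against the change with duration through the covariance over genes, with the 6 rats divided so that no array entered both differences and with an exact test that flips the sign of each rat's leg difference.

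Before the data were examined, 34 lists were fixed, 24 of genes and 10 of cell type markers, and 28 of them had at least 5 measured genes and were tested. The gene lists were fast-fibre contractile, slow-fibre contractile, denervation response, atrophy ubiquitin ligases and FoxO targets, proteasome subunits, autophagy and lysosome, collagens and other matrix proteins, matrix proteases and inhibitors, heat shock proteins and chaperones, stretch and Z-disc response, respiratory chain and ATP synthase, citric acid cycle, fatty acid oxidation, glycolysis and glycogen, calcium release and excitation, insulin-like growth factor and myostatin, inflammatory and acute-phase signalling, oxidative stress and metallothioneins, circadian clock, satellite cell and myogenesis, ribosomal proteins, and unfolded protein and ATF4 response. The marker lists were macrophage, endothelial, fibroblast, adipocyte, smooth muscle and pericyte, and tendon. Embryonic and neonatal sarcomere genes (4 measured), cell division (4), neutrophil (3), T and B lymphocyte (1), Schwann cell and nerve (4) and red blood cell (3) had too few measured genes and were not tested. Each list was compared with all other genes by camera with a preset inter-gene correlation of 0.01, and again with an estimated correlation; fry tested whether its members moved 1 way on balance. Adjusted p-values of lists are over the 28 lists of a comparison. No list kept its camera call with the estimated correlation in any comparison.

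The genes named for a comparison were set by a rule fixed with the lists. They are the 10 largest rises and the 10 largest falls past the threshold, which for leg comparisons needed the same sign in a share of at least 0.75 of the rats, up to 4 members of each list past the threshold, and a fixed set of muscle genes whether or not they passed. Where fewer than 5 genes passed, the 5 with the smallest p were named. The text leaves out some of these genes. Genes named outside the rule are marked as chosen after their values were seen.

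The labels carry a date code, used here as batches 1 to 5. Batches 1, 2 and 4 hold only the shortest window and batch 5 only later ones. Batch 3 holds 4 rats of 6 h to 4 d, 2 of 5 to 8 d and 4 of 9 to 14 d. Both legs of a rat share a batch. Windows are compared as fitted, with the date code as a covariate, and within date code 3. The last 2 rest mostly on batch 3, part of the main fit, so neither is an independent check.

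Alternatives covered the block, the filter on dim probe sets, the probe set that stands for a gene, cyclic loess on top of the deposited values, trended robust variance, array quality weights, the rats in the fit, the date code and leaving out each rat. Others, named below, were chosen after seeing the data. The fits were tested on simulated data, with 100 genes changed by log2 0.50 and 100 by 1.00. Between legs they recovered 91%, 62%, 74% and 97% of the smaller and 100%, 88%, 95% and 98% of the larger changes. These are for 6 h to 4 d, 5 to 8 d, 9 to 14 d and all rats. For windows it was 47% to 70% and 87% to 93%. With fewer changed genes the cutoff is stricter, so 0 calls do not exclude such changes.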

Results

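Expression was measured in both gastrocnemius muscles of 23 paralysed and ventilated rats of an experimental intensive care model, on 46 arrays. Of these rats, 13 were studied for 6 h to 4 d, 4 for 5 to 8 d and 6 for 9 to 14 d. The design asks what passive loading does to paralysed muscle, and how long immobilisation changes it with and without loading. The leading principal component held 42.4% of the variance and the next one 13.0%. Along the leading component the legs of rats 35 and 37, of the shortest window, lay toward the later windows. Of 1035 pairs of arrays, loaded legs 22 and 28 were the closest, with an SD over genes of their difference of 0.14 on the log2 scale, against 0.18 for the closest legs of 1 rat and a median of 0.31. They were kept as separate samples.

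Over all 23 rats, passive loading raised Rbm3, an RNA-binding protein induced by mild cold, by 1.01 on the log2 scale (SE 0.17, 2.02-fold, adjusted p = 0.0051, higher in 20 of 23 rats). It raised Ccn2, connective tissue growth factor, by 0.88 (SE 0.15, 1.84-fold, adjusted p = 0.0051, 21 of 23 rats), and the related matricellular gene Ccn1 by 0.50 (SE 0.12, 19 of 23 rats). Pmepa1, a target and inhibitor of TGF-beta signalling, rose by 0.57 (SE 0.10, adjusted p = 0.0051, 19 of 23 rats), and Fbln2, the matrix glycoprotein fibulin 2, by 0.52 (SE 0.08, adjusted p = 0.0050). Myog, the transcription factor myogenin, fell by 0.44 in the loaded leg (SE 0.09, 1.35-fold, adjusted p = 0.0174, 21 of 23 rats). The steroid-reducing enzyme Akr1c14 had the smallest adjusted p of the named genes, 6.19e-04, and fell by 0.46 in 22 of 23 rats.

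Further rises among these rats were those of Prrt4 (0.63), the monocarboxylate transporter Slc16a6 (0.55), the cartilage and matrix protein Cilp (0.47), Nrep (0.46) and Fbn1, fibrillin 1 (0.43). The calcium channel subunit Cacna2d1 rose by 0.13 (SE 0.03) in 21 of 23 rats. Falls included Pla2g7, an enzyme that degrades platelet-activating factor, which fell by 0.65 (SE 0.16), and the lymphatic growth factor Vegfd, which fell by 0.54 (SE 0.11). Smaller falls were those of aldehyde oxidase Aox1 (-0.51), Sorbs3 (-0.48), the angiotensin receptor Agtr1a (-0.47), Mcpt1l1 (-0.47), Cyp2e1 (-0.46) and Akr1b8 (-0.46). The clock output gene Dbp fell by 0.27 in 22 of 23 rats, Pdk4, which inhibits pyruvate dehydrogenase, fell by 0.19, and Igf1r, the receptor of insulin-like growth factor, fell by 0.17. The muscle ubiquitin ligases did not pass, with log2 differences of -0.07 for Fbxo32 (adjusted p = 0.484) and 0.10 for Trim63 (adjusted p = 0.603). Neither did Chrna1 (-0.18), Mstn (0.16), Ankrd1 (0.60, adjusted p = 0.150), Col1a1 (0.38, adjusted p = 0.144) or the slow myosin Myh7 (-0.13), whose leg differences had an SD of 2.52 between rats.

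Of the 20 measured heat shock proteins and chaperones 0 passed higher, 4 passed lower and 16 did not pass. The 4 were Hsp90aa1, the inducible cytosolic chaperone, which fell by 0.39 (SE 0.08), Hsph1, a nucleotide exchange factor of Hsp70 proteins, which fell by 0.33, and the co-chaperones Stip1 (-0.25) and Chordc1 (-0.19). Adjusted over the list alone 2 were higher and 7 lower; the list's median was -0.10 (camera adjusted p = 0.0029, adjusted p = 0.807 with an estimated correlation). Of 16 collagens and other matrix proteins Fbn1 passed higher and 15 did not pass, 4 were higher and 1 lower adjusted over the list alone, and the median was 0.17 (camera adjusted p = 0.0059, adjusted p = 0.807 with an estimated correlation). Of 17 oxidative stress genes Gpx3, a secreted glutathione peroxidase, fell by 0.28 and catalase, Cat, fell by 0.22, while 15 did not pass. The same 2 were lower adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.0286, or 0.0967 with the legs unblocked; adjusted p = 0.807 with an estimated correlation).

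No member passed among 31 respiratory chain genes (median 0.02, camera adjusted p = 0.0375, unblocked 0.0967, adjusted p = 0.83 with an estimated correlation) or 16 citric acid cycle genes (median 0.04, camera adjusted p = 0.0302, unblocked 0.190, adjusted p = 0.816 with an estimated correlation). Adjusted over the list alone, 0 members of either list passed. Of 7 adipocyte markers 0 passed, 3 were lower adjusted over the list alone, and the median was -0.26 (camera adjusted p = 0.0286, adjusted p = 0.807 with an estimated correlation). The fibroblast markers Pi16 and Mfap5 rose by 0.40 and 0.38. Fry called 0 of the 28 lists here or in any 1 window (smallest adjusted p = 0.144 and 0.150).

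Limma called 269 genes over all 23 rats, 100 higher and 169 lower in the loaded leg, of which 6 differed by at least 1.5-fold (5 higher and 1 lower). After cyclic loess it called 349, 166 higher and 183 lower, so the share of higher genes moved from 37.2% to 47.6%. With the legs unblocked limma called 3 genes, Rbm3, Agtr1a and Akr1c14, with array quality weights 876, without a filter 163, and in the 10 rats of date code 3 it called 1. Leaving out 1 rat gave 103 to 375 genes. The count was 103 without rat 49, 131 without 45, 140 without 43, 151 without 59, 153 without 53, 166 without 11, 167 without 31, 172 without 15, 175 without 17 and 176 without 57. Without rats 21 and 27 together it was 438. The calls of Rbm3, Ccn2, Pmepa1, Slc16a6, Fbln2, Vegfd, Aox1, Sorbs3, Agtr1a, Mcpt1l1, Cyp2e1, Akr1c14, Hsp90aa1, Stip1, Gpx3, Dbp and Myog held with any 1 rat left out, while those of Prrt4 and Mfap5 ended without rat 49, that of Akr1b8 without rat 45, those of Ccn1 and Chordc1 without rat 45 or 49, and those of Cilp, Nrep, Pla2g7, Fbn1, Hsph1, Cat, Igf1r, Pdk4, Cacna2d1 and Pi16 without any 1 of several rats, rat 49 among them.

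**Figure D1:**
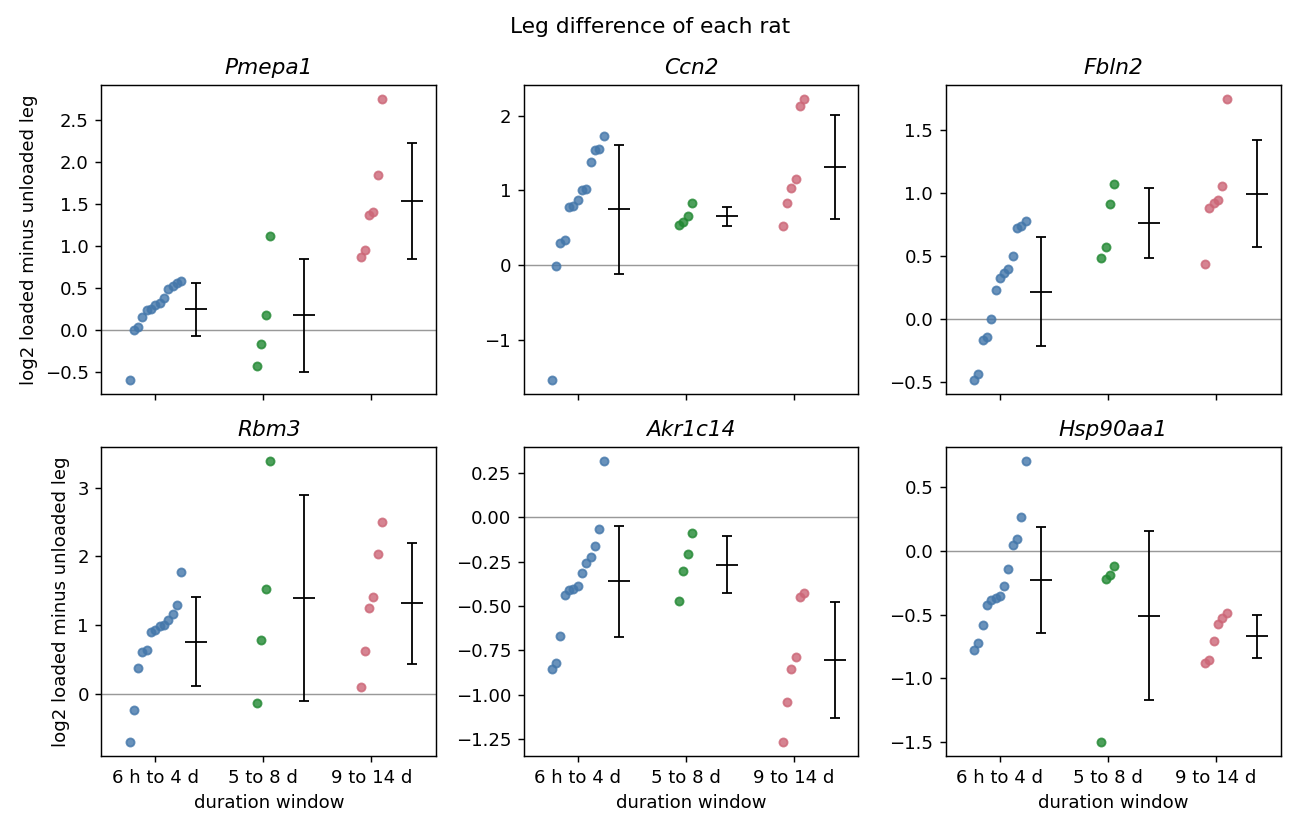
Loaded minus unloaded log2 expression of Pmepa1, Ccn2, Fbln2, Rbm3, Akr1c14 and Hsp90aa1 in each of the 23 rats, by window, with 1 point per rat and bars for mean and SD. At 9 to 14 d the mean difference of Pmepa1 was 1.53, and Akr1c14 was lower in the loaded leg in 22 of 23 rats.

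At 9 to 14 d the legs of 6 rats were compared. Pmepa1 rose by 1.53 (SE 0.19, 2.90-fold, adjusted p = 2.27e-04, 6 of 6 rats), from a level of 8.33 ± 0.31 to 9.86 ± 0.68 (SD, n = 6, limma). Ccn2 rose by 1.32 (SE 0.28, 2.49-fold, adjusted p = 0.0465), Fbln2 by 1.00 (SE 0.16, adjusted p = 0.0036) and Loxl1, which cross-links elastin, by 0.99 (SE 0.19, adjusted p = 0.0258), each in 6 of 6 rats. Akr1c14 fell by 0.81 (SE 0.12, 1.75-fold, adjusted p = 0.0014, 6 of 6 rats), Akr1b8 fell by 0.98 (SE 0.21) and the complement component C3 fell by 0.84 (SE 0.18).

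Other matrix genes that rose were Fbn1 (0.94, SE 0.20, 6 of 6 rats), the collagen Col8a1 (0.91, SE 0.19, 6 of 6 rats), and, chosen after their values were seen, elastin Eln (0.60, SE 0.09, adjusted p = 0.0014) and the TGF-beta binding protein Ltbp2 (0.36, SE 0.08, adjusted p = 0.0470). The fibroblast marker Pi16 rose by 1.07 (SE 0.20, 6 of 6 rats), the microtubule protein Tppp3 by 0.98 (5 of 6 rats), the tight junction gene Cldn4 by 0.69 and Tom1 by 0.61 (5 of 6 rats each). Lgals3, the macrophage lectin galectin 3, fell by 0.74, Zcchc24 fell by 0.59, the matrix protease Mmp11 fell by 0.58, Bbx fell by 0.36 and the kinase Cdk11b fell by 0.31, in 6 of 6 rats each. Of the muscle genes, Fbxo32 (-0.23, adjusted p = 0.328), Myog (-0.25), Myh7 (1.07, adjusted p = 0.658), Ankrd1 (0.67) and Col1a1 (0.51) did not pass.

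Among the lists at 9 to 14 d, collagens and other matrix proteins had a median of 0.35, with Fbn1 passing higher, 15 of 16 not passing and 3 higher adjusted over the list alone (camera adjusted p = 1.47e-04, adjusted p = 0.891 with an estimated correlation). Of 20 chaperones Stip1 and Chordc1 passed lower, by log2 -0.52 (SE 0.10) and -0.49 (SE 0.09), and 18 did not pass. Adjusted over the list alone 2 chaperones were higher and 9 lower, with a median of -0.15 (camera adjusted p = 1.47e-04, adjusted p = 0.834 with an estimated correlation). No ribosomal protein of 33 passed, also when adjusted over the list alone, at a median of -0.09 (camera adjusted p = 1.47e-04, adjusted p = 0.891 with an estimated correlation). In the stretch and Z-disc list 1 of 17 genes passed higher, Ccn2, with 16 not passed, 2 higher adjusted over the list alone and a median of 0.19 (camera adjusted p = 0.0182, adjusted p = 0.496 with an estimated correlation). Of 8 fibroblast markers Pi16 passed, 7 did not and 2 were higher adjusted over the list alone, at a median of 0.27 (camera adjusted p = 0.0395, unblocked 0.123, adjusted p = 0.891 with an estimated correlation). Of 12 macrophage markers 0 passed and 1 was lower adjusted over the list alone, at a median of -0.18 (camera adjusted p = 0.0453, unblocked 0.131, adjusted p = 0.894 with an estimated correlation).

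Limma called 25 genes at 9 to 14 d, 15 higher and 10 lower, of which 11 rose and 5 fell by at least 1.5-fold. The count was 2 with the legs unblocked, Pmepa1 and Eln, 122 with array quality weights, 31 after cyclic loess (16 higher and 15 lower), and 0 both in the window's own 6 rats alone (1206 at unadjusted p under 0.05) and in date code 3 alone (1013). It was 92 without rat 47, 12 without rat 45, 8 without rat 51 or 57 and 6 without rat 49. The calls of Pmepa1, Fbln2, Eln and Akr1c14 held with any 1 rat left out. Those of the other genes named as passing at 9 to 14 d each ended without rat 51 and without at least 1 other rat.

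At 6 h to 4 d and 5 to 8 d limma called 0 genes between the legs. At 6 h to 4 d 1075 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.110, shared by the starch-binding gene Stbd1 (0.43, SE 0.08), Nedd1 (-0.27), Myog (-0.63, SE 0.13), Atf6b (-0.21) and Bace2 (-0.26), each with its sign in 12 of 13 rats. Myh7 differed by -0.98 (SE 0.62), Ankrd1 by 0.50 (SE 0.30) and Fbxo32 by -0.04 (SE 0.07) without passing. At 5 to 8 d 644 genes had an unadjusted p under 0.05; the smallest adjusted p were those of the DNA repair gene Nthl1 (-0.42, 0.0849), C3h15orf48 (1.50, SE 0.28, 0.0849), Tecr of fatty acid elongation (0.42, 0.0885), the laminin receptor subunit Itga7 (-1.02, 0.161) and the lipoprotein receptor Vldlr (-0.68, 0.161), each with its sign in 4 of 4 rats. Col1a1 (0.72), Myh1 (0.39) and Fbxo32 (0.09) did not pass.

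At 6 h to 4 d camera called 4 lists in which 0 members passed, namely slow-fibre contractile (median -0.59, adjusted p = 0.0053), fatty acid oxidation (-0.12, adjusted p = 0.0246), glycolysis and glycogen (0.08, adjusted p = 0.0049) and calcium release (0.05, adjusted p = 0.0049). Each had an adjusted p = 0.876 with an estimated correlation, and adjusted over the list alone 2 glycolytic genes were higher and no member of the other 3 lists passed. At 5 to 8 d camera called 11 lists with 0 members passed, and the medians were 0.10 for the respiratory chain, 0.13 for the citric acid cycle, 0.38 for collagens, -0.17 for chaperones, -0.09 for ribosomal proteins and -0.16 for the unfolded protein response. With an estimated correlation these 11 had adjusted p from 0.728 to 0.857. Adjusted over the list alone, 1 chaperone was higher and 4 were lower, and 5 unfolded protein genes were lower. The other 5 lists were fast-fibre contractile (0.07; unblocked adjusted p = 0.0602), proteasome (0.09), fatty acid oxidation (0.18), fibroblast markers (0.18; unblocked adjusted p = 0.0865) and adipocyte markers (-0.46), with no member passing over the list alone. The count at 6 h to 4 d was 9 with array quality weights, 14 without rat 21, 2 without rat 27, 1 without rat 23 or 37, 2 with loaded legs 22 and 28 averaged and 19 without rats 21 and 27. At 5 to 8 d it was 1182 with array quality weights, 60 without rat 41 and 7 without rat 43.

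The effect of loading was compared between windows directly, and limma called 0 genes for 9 to 14 d minus 6 h to 4 d (717 at unadjusted p under 0.05) and 0 for 5 to 8 d minus 6 h to 4 d (557). Pmepa1 came nearest, with a leg difference of 1.53 at 9 to 14 d and 0.25 at 6 h to 4 d, a gap of 1.29 (SE 0.23, adjusted p = 0.0664). Eln followed with 0.60 against 0.02 (adjusted p = 0.0664), then Wdr62 (gap 0.66), Tom1 (0.61) and Klhl25 (-0.85), each at an adjusted p of 0.271. The gaps of Myog (0.38) and Fbxo32 (-0.19) did not pass. For 5 to 8 d the nearest were Myo1g (-0.84), C3h15orf48 (1.44), Adck2 (0.45) and Tecr (0.41), all at an adjusted p of 0.419, and Id3 (0.56, 0.462). Camera called 7 lists for the later window, of which slow-fibre contractile had a median gap of 1.08 (adjusted p = 5.59e-04) and ribosomal proteins of -0.12 (adjusted p = 1.68e-07), with 0 members passing in either, also adjusted over the list alone, and adjusted p = 0.783 with an estimated correlation for all 7. For 5 to 8 d it called 11, at adjusted p = 0.720 with an estimated correlation. For the later window the count was 1 with array quality weights, 1 without rat 17 or 57, 2 without rat 47, 3 without rat 45 and 1 without rats 17 and 27; for 5 to 8 d it was 526 with array quality weights and 8 without rat 41.

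The unloaded legs of 9 to 14 d were compared with those of 6 h to 4 d. The acetylcholine receptor subunit Chrna1 rose by 4.76 (SE 0.41, 27.1-fold, adjusted p = 7.80e-09), from 8.41 ± 0.89 (SD, n = 13) to 13.17 ± 0.28 (SD, n = 6, limma). The adhesion glycoprotein Emb rose by 4.86 (SE 0.50), the microtubule kinase Dclk1 by 4.73 (SE 0.38), the stretch-responsive titin partner Ankrd1 by 4.29 (SE 0.62) and sarcolipin, Sln, an inhibitor of the calcium pump, by 3.81 (SE 0.36). Myostatin, Mstn, which restrains muscle growth, fell by 2.75 (SE 0.30, 6.72-fold, adjusted p = 1.60e-07). The lactate exporter Slc16a3 fell by 3.18 (SE 0.46) and the water channel of fast fibres Aqp4 fell by 3.48 (SE 0.48).

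Other large rises in the unloaded legs were Slc51a (4.39), Cst7 (4.35), Ctxn3 (4.28), the adrenergic receptor Adra1b (3.88) and the tissue kallikrein Klk1 (3.83). Other large falls were Cmbl (-3.50), musclin Ostn (-3.26), Mss51 (-2.87), the glycolytic regulator Pfkfb1 (-2.87) and Lgi2 (-2.80). Of 13 denervation genes 12 passed higher and 1 did not pass, with the receptor subunits Chrnd (3.30) and fetal Chrng (2.79), the adhesion molecule Ncam1 (3.08) and Myog (2.70) among them. Adjusted over the list alone 12 were higher, at a median of 2.20 (camera adjusted p = 1.02e-07, adjusted p = 0.20 with an estimated correlation). Of 11 satellite cell and myogenesis genes 6 passed higher, 2 lower and 3 did not pass, likewise 6 and 2 adjusted over the list alone. They included the fusion gene Mymk (2.86), Myf5 (2.21) and Myod1 (2.02), at a median of 0.21 (camera adjusted p = 0.354, adjusted p = 0.612 with an estimated correlation).

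Ribosomal proteins passed higher in these legs in 32 of 33 cases and 1 did not pass, also adjusted over the list alone, at a median of 0.67 (camera adjusted p = 8.52e-22, adjusted p = 0.0937 with an estimated correlation). Rpl3 rose by 2.02 (SE 0.14, 4.06-fold), and Rps19, whose probe sets are uncertain, by 1.30. All 16 citric acid cycle genes passed lower, over the list alone too, at a median of -0.67 (camera adjusted p = 5.13e-08, adjusted p = 0.38 with an estimated correlation), and the mitochondrial Idh2 fell by 1.15 (SE 0.26). Of 19 glycolysis and glycogen genes 15 passed lower and 4 did not, with 15 lower adjusted over the list alone and a median of -0.80 (camera adjusted p = 5.13e-08, adjusted p = 0.207 with an estimated correlation). Among them Fbp2 fell by 2.03, Pfkm fell by 1.27 and the insulin-responsive glucose transporter Slc2a4 fell by 1.50. Of 31 respiratory chain genes 24 passed lower, 7 did not and 27 were lower adjusted over the list alone, with Ndufs7 (-1.07) and Cox8b (-1.03) among them and a median of -0.56 (camera adjusted p = 3.77e-11, adjusted p = 0.441 with an estimated correlation). Of 20 fatty acid oxidation genes 9 passed lower, 11 did not and 10 were lower adjusted over the list alone, Hadh by log2 -1.73, at a median of -0.46 (camera adjusted p = 9.40e-04, adjusted p = 0.612 with an estimated correlation).

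Fast-fibre contractile genes fell in 7 of 12 cases with 5 not passed, 7 adjusted over the list alone, at a median of -0.46 (camera adjusted p = 2.38e-04, adjusted p = 0.280 with an estimated correlation). Examples are Mybpc2 (-1.98), the myosin kinase Mylk2 (-1.84), Actn3 (-1.13) and the fast myosin Myh4 (-0.58, SE 0.23). In the list of atrophy ligases and FoxO targets 3 of 17 passed higher, 9 lower and 5 did not, the same counts of 3 and 9 adjusted over the list alone, at a median of -0.52 (camera adjusted p = 0.0067, adjusted p = 0.344 with an estimated correlation). The mTOR inhibitor Ddit4 fell by 1.78, Foxo1 fell by 1.77 and Sesn1 fell by 1.61, while the repressor Tgif1 rose by 1.09. Fbxo32 (-0.12, adjusted p = 0.474) and Trim63 (-0.37, adjusted p = 0.364) did not pass, from levels of 13.05 and 12.16 to 12.92 and 11.79. Without untreated rats an earlier rise cannot be seen. Of 16 matrix proteins 1 passed higher, 5 lower and 10 did not, with 5 lower adjusted over the list alone and a median of -0.36 (camera adjusted p = 0.0213, adjusted p = 0.612 with an estimated correlation); Col1a1 fell by 1.80, Fn1 fell by 1.29 and Sparc fell by 1.14. Of 20 chaperones 12 passed higher, 1 lower and 7 did not, 13 and 2 adjusted over the list alone, at a median of 0.44 (camera adjusted p = 0.0331, adjusted p = 0.612 with an estimated correlation). Hspb8 rose by 1.30, Hsp90aa1 by 1.29 and Hsph1 by 1.24, and Hspb6 fell by 1.11. Of 13 clock genes 6 passed lower and 7 did not, 6 adjusted over the list alone, Per1 by log2 -1.13, at a median of -0.32 (camera adjusted p = 0.0213, adjusted p = 0.207 with an estimated correlation).

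The remaining lists were not called by camera in the unloaded legs at 9 to 14 d, and their members passed as follows, with the counts adjusted over the list alone equal unless given. Slow-fibre contractile genes passed higher in 1 (Sln) and lower in 4 of 14 cases, Myl3 at -2.77 (SE 1.00) and Myh7 at -2.76 (SE 0.89), with a median of -0.91. Proteasome subunits passed higher in 3 of 30 cases, none adjusted over the list alone, with a median of 0.15; after cyclic loess limma called 0 of them. Autophagy and lysosome genes passed higher in 5 and lower in 2 of 20 cases, the protease Ctsl at 1.67, with a median of 0.09 that was -0.01 after cyclic loess, where 5 were higher and 4 lower. Matrix proteases passed lower in 3 of 12 (median -0.17), and stretch and Z-disc genes higher in 3 and lower in 4 of 17. The stretch list had a median of 0.06 and a mean of 0.28 while camera's direction was down, and its median was -0.05 after cyclic loess. Calcium release genes passed higher in 2 and lower in 6 of 13 (7 lower over the list alone, median -0.41), and insulin-like growth factor and myostatin genes higher in 7 and lower in 5 of 15, with a median of 0.28 and a mean of 0.01 where camera's direction was down. Follistatin, Fst, which binds myostatin, was among the 7 with 1.99, and the stretch-activated channel Piezo1, of the stretch list, rose by 2.35. Inflammatory genes passed higher in 4 (3 over the list alone) and lower in 1 of 15, with a median of 0.16 and mean of 0.14 where camera's direction was down. Oxidative stress genes passed higher in 9 and lower in 2 of 17 (median 0.39). Unfolded protein and ATF4 genes passed higher in 7 and lower in 3 of 16 (median 0.24), with Atf4 at -1.26.

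Camera called 0 of the 6 marker lists in this comparison. Of 12 macrophage markers 6 passed higher and 6 did not, also adjusted over the list alone, with Cd68 at 1.41 (SE 0.40), Adgre1 at 1.34 (SE 0.27) and a median of 0.67 (camera adjusted p = 0.0910). Lower members passed for 3 of 6 endothelial markers (Cdh5 -0.34, median -0.27), 2 of 8 fibroblast markers (Pi16 -1.48, median -0.32) and 1 of 7 adipocyte markers (median -0.24). Smooth muscle and pericyte markers passed higher in 1 and lower in 2 of 6 (median -0.33), and tendon markers higher in 1 and lower in 1 of 5 (median -1.01), all the same adjusted over the list alone. With an estimated correlation the adjusted p of these marker lists lay between 0.612 and 0.738. Fry called 13 of the 28 lists.

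Limma called 4232 genes in the unloaded legs at 9 to 14 d, 2663 higher and 1569 lower, of which 1228 rose and 549 fell by at least 1.5-fold. After cyclic loess 2243 were higher and 2003 lower, or 52.8% higher against 62.9%, and the median of all genes moved from 0.07 to 5.92e-04. With the date code as a covariate 2177 passed (1420 higher and 757 lower) and within date code 3 904 passed (659 and 245). All 60 named genes that passed kept their sign in these overlapping fits, 46 passed with the covariate and 31 within date code 3. Chrna1 was then at 4.39 and 4.47, Mstn at -2.31 and -2.28 and Rpl3 at 1.84 and 1.81. The calls of Myl3 (-0.46 with the covariate), Myh7 (-0.82), Myh4 (-0.73), Myod1 (0.64), Ddit4 (-0.91), Tgif1 (0.73), Idh2 (-0.75), Fbp2 (-1.11), Col1a1 (-0.77), Fn1 (-0.35), Sparc (-0.47), Hsp90aa1 (0.86), Cdh5 (-0.37) and Pi16 (-0.81) ended with it. Trim63, which had not passed, passed lower with the covariate (-1.07, adjusted p = 0.0393) and not within date code 3 (-0.99, adjusted p = 0.192). Leaving out 1 rat ended the calls of Myl3 (rat 49 or 51), Myh7 (rat 51), Fn1 (rat 57) and Myh4 (any 1 of 13 rats).

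List medians in the unloaded legs at 9 to 14 d, with the date code as a covariate and within date code 3, were 1.75 and 1.68 for denervation, 0.65 and 0.66 for ribosomal proteins, -0.49 and -0.51 for the citric acid cycle, -0.62 and -0.61 for glycolysis, and -0.32 and -0.36 for the respiratory chain. They were -0.30 and -0.32 for fatty acid oxidation, -0.36 and -0.43 for fast-fibre genes, -0.31 and -0.32 for atrophy ligases, 0.43 and 0.36 for chaperones, -0.34 and -0.35 for the clock, -0.12 and -0.15 for matrix proteins and 1.01 and 0.87 for macrophage markers. The median turned positive for slow-fibre genes (0.29 and 0.07), matrix proteases (0.08 and 0.02) and tendon markers (0.08 and 0.0079), and with the covariate for fibroblast markers (0.01, against -0.07 within date code 3). It turned negative for proteasome subunits (-0.21 and -0.17) and, with the covariate, for autophagy and lysosome (-0.0017, against 0.02 within date code 3), and for inflammatory genes it was 0.56 and 0.49. With the covariate members passed lower in 7 of 16 citric acid cycle genes, 11 of 31 respiratory chain genes, 10 of 19 glycolysis genes, 3 of 20 fatty acid oxidation genes, 6 of 12 fast-fibre genes and 3 of 13 clock genes. Higher were 10 of 13 denervation genes, 33 of 33 ribosomal proteins and 8 of 12 macrophage markers. Chaperones passed higher in 10 and lower in 1 of 20 cases, atrophy ligases higher in 1 and lower in 6 of 17, and limma called 0 of 16 matrix proteins. It called 0 endothelial, 0 fibroblast, 0 smooth muscle and 0 tendon markers and 1 adipocyte marker, which was lower.

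**Figure D2:**
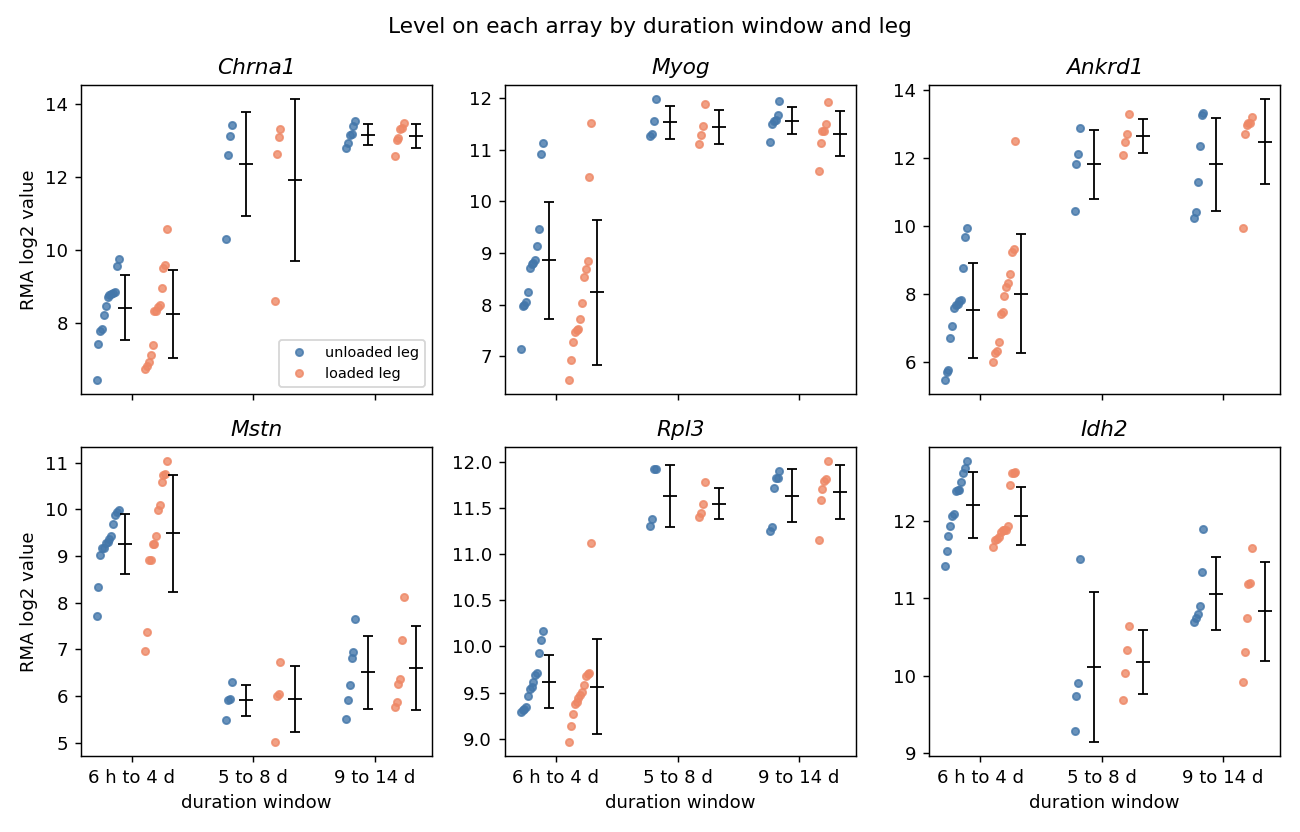
Log2 expression of Chrna1, Myog, Ankrd1, Mstn, Rpl3 and Idh2 in each leg, by window, with 1 point per array, unloaded and loaded legs apart and mean and SD marked. Chrna1 in unloaded legs was 8.41 at 6 h to 4 d and 13.17 at 9 to 14 d, and Mstn was 9.26 and 6.51.

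The unloaded legs of 5 to 8 d were compared with those of 6 h to 4 d. Ankrd1 rose by 4.30 (SE 0.71, 19.7-fold, adjusted p = 9.79e-05), from 7.51 ± 1.41 (SD, n = 13) to 11.81 ± 1.02 (SD, n = 4, limma). Chrna1 rose by 3.95 (SE 0.47), Emb by 4.14 (SE 0.58), the tubulin Tubb6 by 3.92 (SE 0.44), Ppp1r14c by 3.60, Sln by 3.12, Akip1 by 3.10 and Gpnmb by 3.08. Mstn fell by 3.35 (SE 0.34, adjusted p = 6.17e-07), to a mean of 5.91 that lies below the median of every array, Ostn fell by 3.80, Gpd1 fell by 3.31, Pfkfb1 fell by 3.29 and Cmbl fell by 3.25. The sodium pump subunit Atp1b2 (-3.13), Aqp4 (-3.04), Ky (-3.01) and the Z-disc protein Ldb3 (-2.87) fell as well.

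Of 13 denervation genes 11 passed higher and 2 did not, 11 adjusted over the list alone, with Myog at 2.67 and Ncam1 at 2.59. The median was 1.74 (camera adjusted p = 1.71e-06, adjusted p = 0.241 with an estimated correlation). Ribosomal proteins passed higher in 32 of 33 cases with 1 not passed, 32 over the list alone, with Rpl3 at 2.02. Its median was 0.57 (camera adjusted p = 2.30e-19, adjusted p = 0.146 with an estimated correlation). All 16 citric acid cycle genes passed lower, also adjusted over the list alone, with Idh2 at -2.10. The list's median was -0.83 (camera adjusted p = 1.89e-10, adjusted p = 0.263 with an estimated correlation). Of 31 respiratory chain genes 27 passed lower and 4 did not, 28 adjusted over the list alone. Members had a median of -0.66 (camera adjusted p = 4.43e-15, adjusted p = 0.263 with an estimated correlation). Of 19 glycolysis and glycogen genes 1 passed higher, 14 lower and 4 did not, the same adjusted over the list alone. The list had a median of -0.87 (camera adjusted p = 3.52e-08, adjusted p = 0.241 with an estimated correlation). Fbp2 fell by 2.30, Phkg1 fell by 2.08 and the glycogen synthase Gys1 fell by 1.79. Of 20 fatty acid oxidation genes 9 passed lower and 11 did not, 11 lower adjusted over the list alone, with Hadh at -2.31. The median was -0.45 (camera adjusted p = 9.89e-05, adjusted p = 0.440 with an estimated correlation).

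Of 16 matrix proteins 12 passed lower and 4 did not, 13 adjusted over the list alone, with Col1a1 at -2.85 (SE 0.60), Fn1 at -2.58 and Postn at -1.78. Its median was -1.12 (camera adjusted p = 1.47e-06, adjusted p = 0.285 with an estimated correlation). Of 8 fibroblast markers 7 passed lower, all 8 adjusted over the list alone, at a median of -1.10 (camera adjusted p = 9.89e-05, adjusted p = 0.263 with an estimated correlation). Tendon markers passed higher in 1 and lower in 4 of 5 cases, also adjusted over the list alone, with Chad at -2.95, Kera at -2.79 and Fmod at -2.41. The list's median was -2.41 (camera adjusted p = 0.0315, adjusted p = 0.354 with an estimated correlation). Of 12 macrophage markers 2 passed lower and 10 did not, 0 adjusted over the list alone, with C1qc at -1.01. Members had a median of -0.48 (camera adjusted p = 0.0361, adjusted p = 0.584 with an estimated correlation). The red cell gene Hbb-b1 fell by 2.22 (SE 0.55); its list was not tested. Proteasome subunits passed higher in 9 of 30 cases with 21 not passed, 9 adjusted over the list alone, with Psma4 at 1.00 and Psmb4 at 0.82. The list had a median of 0.45 (camera adjusted p = 0.0042, adjusted p = 0.584 with an estimated correlation). Chaperones passed higher in 10 and lower in 2 of 20 cases, 11 and 2 over the list alone. The median was 0.35 (camera adjusted p = 0.0424, adjusted p = 0.491 with an estimated correlation). Fast-fibre genes passed lower in 7 of 12 cases, 8 adjusted over the list alone, with Mylk2 at -2.08. Its median was -0.54 (camera adjusted p = 9.89e-05, adjusted p = 0.263 with an estimated correlation). Atrophy ligases and FoxO targets passed higher in 1 and lower in 6 of 17 cases, 3 and 8 adjusted over the list alone, with Ddit4 at -1.93 and Sesn1 at -1.82. The list's median was -0.27 (camera adjusted p = 0.0315, adjusted p = 0.330 with an estimated correlation). Fbxo32 (0.16) and Trim63 (0.30) did not pass. Camera also called matrix proteases (-0.51), calcium release (-0.49) and the clock (-0.24) lower, with 5 of 12, 6 of 13 and 4 of 13 members lower and 2 calcium genes higher, the same adjusted over the list alone. Proteases and the clock had an adjusted p = 0.263 with an estimated correlation, and calcium release one of 0.309.

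Limma called 3337 genes in this comparison, 2190 higher and 1147 lower (1026 and 664 by at least 1.5-fold), and fry called 19 lists. After cyclic loess 1606 were higher and 1647 lower, or 49.4% against 65.6% higher, and with array quality weights 5375 passed. With the date code as a covariate 757 passed (501 higher and 256 lower) and within date code 3, with 4 and 2 rats, 16 (10 and 6). Of 38 named genes that passed, 38 kept their sign with the covariate and 23 passed, and within date code 3 36 kept it and 1, Cmbl, passed. The 2 exceptions were Psmb4 at -0.11 and C1qc at 0.03. Chrna1 was 3.46 and 3.31, Mstn -2.89 and -2.94 and Col1a1 -1.78 and -1.73. List medians were 1.29 and 1.21 for denervation, 0.56 and 0.48 for ribosomal proteins, -0.64 and -0.59 for the citric acid cycle, -0.40 and -0.32 for the respiratory chain, -0.80 and -0.72 for glycolysis, -0.43 and -0.31 for fatty acid oxidation and -0.61 and -0.54 for matrix proteins. They were -0.80 and -0.75 for fibroblast markers, -1.15 and -0.85 for tendon markers, -0.07 and 0.26 for macrophage markers, 0.01 and -0.10 for the proteasome, 0.42 and 0.44 for chaperones, -0.46 and -0.53 for fast-fibre genes, -0.22 and -0.24 for atrophy ligases, -0.38 and -0.30 for matrix proteases, -0.38 and -0.44 for calcium release and -0.30 and -0.33 for the clock. Slow-fibre genes, with a median of -0.55 (1 of 14 higher and 1 lower), had 0.57 and 1.14. With the covariate lower members were 1 of 16 matrix proteins, 1 of 8 fibroblast markers, 8 of 16 citric acid cycle genes, 7 of 31 respiratory chain genes, 8 of 19 glycolysis genes, 2 of 20 fatty acid oxidation genes, 3 of 12 fast-fibre genes and 3 of 17 atrophy ligases. Limma called 0 tendon markers, 0 macrophage markers and 0 proteasome subunits. Higher were 5 of 13 denervation genes, 29 of 33 ribosomal proteins and 4 of 20 chaperones, with 1 chaperone lower. Matrix proteases, the clock and calcium release had 1, 1 and 2 lower members, and 2 calcium genes passed higher. The calls of Col1a1 (adjusted p = 0.147), Fn1 (adjusted p = 0.127), Chad, Kera, Fmod, Psma4, Psmb4, C1qc, Hbb-b1, Gpnmb, Aqp4, Myog, Fbp2, Gys1 and Ddit4 ended with it. Trim63, which had not passed, passed higher without rat 43 (0.91) and with array quality weights (0.97), and Fbxo32 with these weights (0.37). The calls of Psma4 and C1qc ended without rat 55 and that of Psmb4 without rat 53 or 55.

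The loaded legs were compared between the same windows. At 9 to 14 d Emb rose by 5.27 (SE 0.55, adjusted p = 1.87e-07), from a mean of 5.76 that lies below the median of every array, and Chrna1 by 4.90 (SE 0.59, 29.8-fold, adjusted p = 9.43e-07), from 8.24 ± 1.21 (SD, n = 13) to 13.14 ± 0.33 (SD, n = 6, limma). Dclk1 rose by 4.79, Ankrd1 by 4.46 (SE 0.69), Cst7 by 4.07, Sln by 4.01, Ppp1r14c by 3.77 and Chrnd by 3.67. Ostn fell by 3.91, Slc16a3 fell by 3.75 (SE 0.52), Pfkfb1 fell by 3.44, Aqp4 fell by 3.39, Cmbl fell by 3.22, Mstn fell by 2.89 (SE 0.51) and Lynx1, a modulator of nicotinic receptors, fell by 2.76. Myh3, the embryonic myosin, rose by 1.99 (SE 0.51); its list had too few genes to test.

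In these loaded legs 12 of 13 denervation genes passed higher and 1 did not, 12 adjusted over the list alone, with Ncam1 at 3.23 and Myog at 3.08. Members had a median of 2.32 (camera adjusted p = 2.37e-07, adjusted p = 0.232 with an estimated correlation). Ribosomal proteins passed higher in 32 of 33 cases, 32 over the list alone, with Rpl3 at 2.12 and Rps20, whose probe sets are uncertain, at 0.91. The list had a median of 0.59 (camera adjusted p = 1.09e-15, adjusted p = 0.232 with an estimated correlation). Of 31 respiratory chain genes 28 passed lower and 3 did not, 30 adjusted over the list alone. The median was -0.65 (camera adjusted p = 1.09e-15, adjusted p = 0.236 with an estimated correlation). All 16 citric acid cycle genes passed lower, also adjusted over the list alone, with Idh2 at -1.22. Its median was -0.68 (camera adjusted p = 3.95e-10, adjusted p = 0.236 with an estimated correlation). Of 19 glycolysis genes 1 passed higher, 15 lower and 3 did not, the same adjusted over the list alone, with Fbp2 at -2.73 and Pfkm at -1.40. The list's median was -0.87 (camera adjusted p = 4.19e-09, adjusted p = 0.232 with an estimated correlation). Of 20 fatty acid oxidation genes 7 passed lower, also adjusted over the list alone, with Hadh at -1.65. Members had a median of -0.29 (camera adjusted p = 0.0069, adjusted p = 0.826 with an estimated correlation). Of 12 fast-fibre genes 9 passed lower and 3 did not, 9 adjusted over the list alone, with Mybpc2 at -2.38, Mylk2 at -2.09 and Actn3 at -1.47. The list had a median of -0.36 (camera adjusted p = 3.09e-05, adjusted p = 0.232 with an estimated correlation). Of 17 atrophy ligases and FoxO targets 3 passed higher, 9 lower and 5 did not, 3 and 10 adjusted over the list alone. The median was -0.58 (camera adjusted p = 5.79e-04, adjusted p = 0.232 with an estimated correlation). In that list Sesn1 fell by 1.81, Ddit4 fell by 1.80 and Foxo1 fell by 1.70, the ligase Fbxo30 rose by 1.33, and Fbxo32 (-0.31) and Trim63 (-0.43) did not pass. Calcium release genes passed higher in 2 and lower in 6 of 13 cases, 2 and 8 adjusted over the list alone. Its median was -0.45 (camera adjusted p = 0.0208, adjusted p = 0.576 with an estimated correlation).

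Outside the called lists, Mymk rose by 3.00, Myf5 by 2.44, Fst by 2.65, Piezo1 by 2.26, the Z-disc protein Csrp3 by 2.32 (SE 0.62) and Hsp90aa1 by 0.84 (SE 0.27), and Col1a1 fell by 1.50 (SE 0.55). Slow myosin Myh7 (-0.72, adjusted p = 0.569) did not pass. Of 16 matrix proteins 1 passed higher and 3 lower, 0 adjusted over the list alone, at a median of -0.03 (camera adjusted p = 0.240), and 4 of 12 macrophage markers passed higher (2 after cyclic loess), also over the list alone, at a median of 0.52 (camera adjusted p = 0.256). Of 5 tendon markers 1 passed higher and 4 lower (median -1.61).

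Limma called 4110 genes in the loaded legs at 9 to 14 d, 2696 higher and 1414 lower (1098 and 592 by at least 1.5-fold), and fry called 14 lists. After cyclic loess 2122 were higher and 1898 lower, or 52.8% against 65.6% higher. With the covariate 1862 passed (1199 higher and 663 lower) and within date code 3 453 (288 and 165). All 38 named genes that passed kept their sign both ways, 29 passed with the covariate and 24 within date code 3. Chrna1 was 3.81 and 4.13, Ankrd1 3.78 and 3.74, Mstn -1.73 and -1.74 and Rpl3 1.70 and 1.73. List medians were 1.81 and 1.81 for denervation, 0.48 and 0.52 for ribosomal proteins, -0.46 and -0.46 for the respiratory chain, -0.64 and -0.66 for the citric acid cycle, -0.61 and -0.66 for glycolysis, -0.44 and -0.48 for fast-fibre genes, -0.42 and -0.41 for atrophy ligases, -0.50 and -0.49 for fatty acid oxidation, -0.33 and -0.28 for calcium release and 0.85 and 0.75 for macrophage markers. For matrix proteins they turned positive (0.15 and 0.20), as they did for fibroblast markers (0.10 and 0.15) from -0.16, and for the proteasome they turned negative (-0.17 and -0.19) from 0.23. With the covariate lower members were 14 of 16 citric acid cycle genes, 19 of 31 respiratory chain genes, 10 of 19 glycolysis genes, 6 of 20 fatty acid oxidation genes, 6 of 12 fast-fibre genes, 4 of 17 atrophy ligases and 3 of 13 calcium release genes, with 1 atrophy and 1 calcium gene higher. Higher were 9 of 13 denervation genes, 29 of 33 ribosomal proteins and 2 of 12 macrophage markers, and limma called 0 of 16 matrix proteins. The calls of Ostn, Mstn, Myh3, Myog, Ddit4, Fbxo30, Col1a1, Csrp3 and Hsp90aa1 ended with the covariate, and that of Col1a1 also without rat 45, 47, 57 or 59. Fbxo32, which had not passed, passed lower after cyclic loess (-0.41) and without rat 33 (-0.34), 45 (-0.42) or 47 (-0.39).

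**Figure D3:**
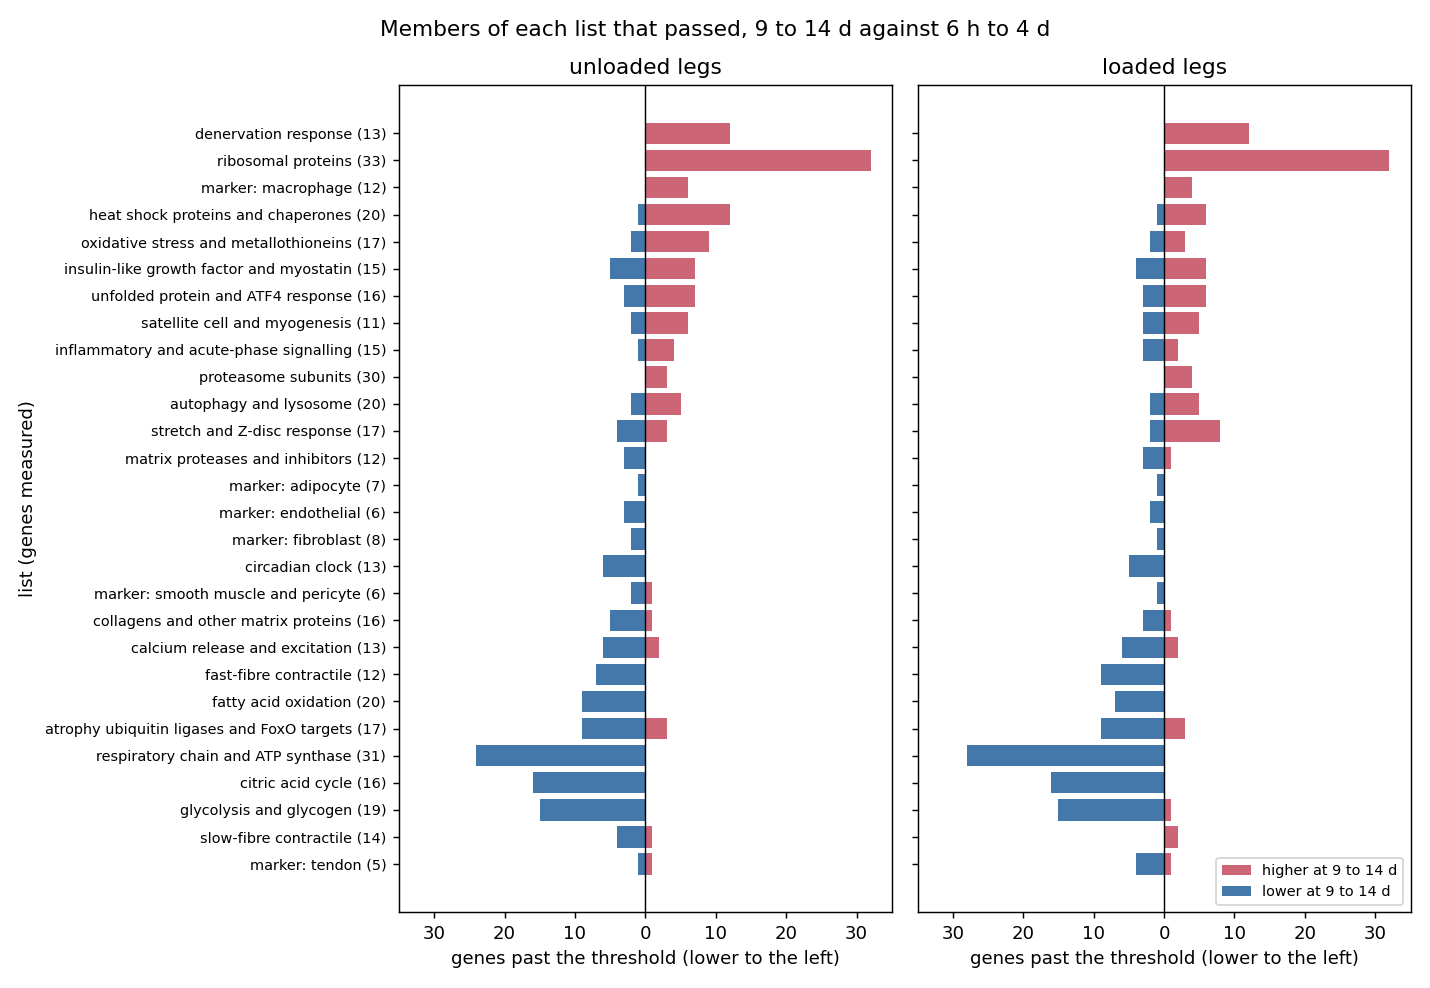
Number of measured members of each gene list that passed higher or lower at 9 to 14 d against 6 h to 4 d, in unloaded and in loaded legs. Of 33 ribosomal proteins 32 passed higher in both legs, and all 16 citric acid cycle genes passed lower in both. With the date code as a covariate 7 citric acid cycle genes passed lower in unloaded and 14 in loaded legs.

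At 5 to 8 d the loaded legs showed Ankrd1 higher by 4.63 (SE 0.79, 24.7-fold, adjusted p = 1.46e-04), at 12.63 ± 0.50 (SD, n = 4) against 8.01 ± 1.74 (SD, n = 13, limma), and Emb higher by 4.36 (SE 0.64). Ppp1r14c rose by 3.78, Chrna1 by 3.68 (SE 0.68), Tubb6 by 3.67, Sln by 3.54, Myog by 3.20 and the AMP deaminase Ampd3 by 2.93 (SE 0.82). Ostn fell by 4.36, Pfkfb1 fell by 3.91 (SE 0.44), Gpd1 fell by 3.69, Mss51 fell by 3.59, Mstn fell by 3.54 (SE 0.59) and Mlf1 fell by 3.17. Col1a1 fell by 2.34 (SE 0.63), and the tendon proteoglycans Kera (-2.52) and Fmod (-2.21) fell as well.

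Proteasome subunits passed higher in 22 of 30 cases with 8 not passed, 25 adjusted over the list alone, with Psma4 at 1.07, Psmb4 at 0.89 and Psmd8 at 0.89. The list's median was 0.60 (camera adjusted p = 6.17e-05, adjusted p = 0.617 with an estimated correlation). Denervation genes passed higher in 11 of 13 cases, 12 adjusted over the list alone, with Gadd45a at 2.55 and Runx1 at 2.49. Members had a median of 1.84 (camera adjusted p = 2.66e-05, adjusted p = 0.315 with an estimated correlation). Ribosomal proteins passed higher in 29 of 33, 30 over the list alone, with Rpl3 at 1.98. The list had a median of 0.48 (camera adjusted p = 1.41e-11, adjusted p = 0.315 with an estimated correlation). Members passed lower in 25 of 31 respiratory chain genes (26 adjusted over the list alone, median -0.63, camera adjusted p = 9.23e-15), 15 of 16 citric acid cycle genes (16 over the list alone, Idh2 at -1.88, median -0.73, camera adjusted p = 1.39e-10) and 14 of 19 glycolysis genes, with 1 higher (15 and 1 over the list alone, Fbp2 -2.94, Phkg1 -2.10, median -0.95, camera adjusted p = 1.25e-08). These 3 lists each had an adjusted p = 0.315 with an estimated correlation. Of 16 matrix proteins 5 passed lower, also over the list alone, at a median of -0.74 (camera adjusted p = 1.26e-04, adjusted p = 0.416 with an estimated correlation), beside 4 of 8 fibroblast markers (median -0.92) and 4 of 5 tendon markers (median -2.21), the same over the list alone and both at an adjusted p = 0.315 with an estimated correlation. Of 17 atrophy ligases and FoxO targets 2 passed higher and 6 lower, also over the list alone, with Sesn1 at -1.79. The median was -0.08 (camera adjusted p = 0.0361, adjusted p = 0.315 with an estimated correlation), and Fbxo32 (0.29) and Trim63 (0.56, adjusted p = 0.105) did not pass. Calcium release genes passed higher in 2 and lower in 7 of 13, also over the list alone, with the chloride channel Clcn1 at -1.68 and the junction protein Jph2 at -1.66. Its median was -0.51 (camera adjusted p = 0.0088, adjusted p = 0.373 with an estimated correlation). Camera also called fast-fibre genes (5 of 12 lower, 6 adjusted over the list alone, median -0.42, camera adjusted p = 8.39e-04), matrix proteases (3 of 12 lower, median -0.42, camera adjusted p = 0.0098), fatty acid oxidation (3 of 20 lower, median -0.26, camera adjusted p = 0.0099) and inflammatory signalling (1 of 15 higher and 3 lower, median -0.20, camera adjusted p = 0.0446). The last 3 had the same members adjusted over the list alone, and the 4 lists had an adjusted p = 0.315, 0.373, 0.63 and 0.63 with an estimated correlation. Of 12 macrophage markers 2 passed lower, also adjusted over the list alone, at a median of -0.40 (camera adjusted p = 0.0361, adjusted p = 0.63 with an estimated correlation), and of 7 adipocyte markers limma called 0, also over the list alone, at a median of -0.39 (camera adjusted p = 0.0361, adjusted p = 0.527 with an estimated correlation).

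Limma called 3620 genes, 2503 higher and 1117 lower (1060 and 622 by at least 1.5-fold), and fry called 16 lists. After cyclic loess 1724 were higher and 1642 lower, or 51.2% against 69.1% higher. Then 13 of 30 proteasome subunits were higher (median 0.44), and 8 of 20 fatty acid oxidation genes (median -0.43) and 8 of 16 matrix proteins (median -0.87) were lower. With the covariate 850 passed (557 higher and 293 lower), and within date code 3 limma called 0 (1166 at unadjusted p under 0.05). All 29 named genes that passed kept their sign both ways, 13 passed with the covariate and 0 within date code 3. Ankrd1 was 3.80 and 3.87, Chrna1 2.37 and 1.74, Mstn -2.24 and -2.22 and Col1a1 -1.52 and -1.82. List medians were 0.16 and 0.17 for the proteasome, 0.93 and 0.82 for denervation, 0.41 and 0.34 for ribosomal proteins, -0.52 and -0.56 for the respiratory chain, -0.68 and -0.69 for the citric acid cycle, -0.74 and -0.63 for glycolysis, -0.39 and -0.45 for matrix proteins, -0.59 and -0.60 for fibroblast markers, -2.26 and -2.35 for tendon markers, -0.22 and -0.17 for atrophy ligases and -0.47 and -0.56 for calcium release. They were -0.58 and -0.60 for fatty acid oxidation, -0.20 and -0.03 for matrix proteases, 0.0085 and -0.06 for inflammatory signalling, -0.05 and 0.12 for macrophage markers, -0.30 and -0.26 for fast-fibre genes and -0.38 and -0.33 for adipocyte markers. With the covariate limma called 0 of 30 proteasome subunits, 0 of 16 matrix proteins, 0 of 8 fibroblast markers, 0 macrophage markers and 0 matrix proteases. Higher were 2 of 13 denervation genes and 20 of 33 ribosomal proteins. Lower were 12 of 31 respiratory chain genes, 12 of 16 citric acid cycle genes, 6 of 19 glycolysis genes, 2 of 5 tendon markers, 1 of 17 atrophy ligases, 1 of 12 fast-fibre genes, 3 of 20 fatty acid oxidation genes, 1 of 15 inflammatory genes and 4 of 13 calcium release genes, with 2 calcium genes higher. The calls of Chrna1, Sln, Myog, Ampd3, Ostn, Mss51, Mstn, Gadd45a, Runx1, Psma4, Psmb4, Psmd8, Fbp2, Phkg1, Jph2 and Col1a1 ended with it. Those of Psmd8 and Jph2 ended also without rat 41. Trim63, which had not passed, passed higher without rat 43 (0.78), with only the 2 windows fitted (0.56) and with array quality weights (0.68), and Fbxo32 with these weights (0.39).

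Whether loading moved genes against the change with duration was tested at 9 to 14 d with separate rats in the 2 differences. Over 9289 genes the covariance of the loading effect with the change in unloaded legs was -0.0137 (r = -0.118 across genes, which are not independent replicates), averaged over the 20 ways to divide the 6 rats. The exact test over 64 sign flips gave p = 0.188 for the covariance and 0.219 for the correlation (two-sided, 1 relation). Over the 4232 genes that changed with duration the covariance was -0.0292 (r = -0.172, exact p = 0.188). With the same rats in both differences it was -0.0220 (exact p = 0.0625), where shared arrays alone gave -0.0092 in 100 simulations with no loading effect.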

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

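The tests of whether arrays of loaded legs 22 and 28 share an RNA, of connective tissue in the biopsy and of single rats behind the matrix genes were chosen after the result was seen. For the temperature test and the 2 tests of the matrix genes, what would count as an answer was made stricter after their values were known. For the 2 differences between windows in the effect of loading, a swap of legs had been written down in advance, and rats were exchanged between the windows instead.

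Loaded leg 28 of rat 27 lay closer to loaded leg 22 of rat 21 than any legs of 1 rat lay to each other. The SD over genes of their difference was 0.1449, against 0.184 for the closest legs of 1 rat and 0.438 between leg 28 and its own unloaded leg, which is what a mislabelled sample or one RNA on 2 arrays would give, although no probe set had identical values. Of 306 genes that differed by at least 1 log2 between the unloaded legs of these rats, 35.6% lay nearer rat 27 in loaded leg 28 and 36.3% in loaded leg 22, where the median over 156 ordered pairs of rats was 80.6% nearer a leg's own rat. Of the 8 pairs as low, the tested one included, 7 were of loaded legs 22 or 28 and 1 was of another leg. The 35.6% fell between the bounds set before the test, so it does not tell a like stage of both rats apart from an exchanged sample. The unloaded legs of rats 21 and 27 differed by an SD of 0.439, against a median of 0.312 between legs of 1 rat. That is not what a like stage would give, but it rests on 1 array of each rat and does not settle the question.

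Over all 23 rats Rbm3 and Cirbp, both induced by mild cold, rose by 1.01 and 0.42 in the loaded leg (adjusted p = 0.0051 and 0.0136), and 4 chaperones fell; Cirbp was chosen after its values were seen. All 6 genes passed after cyclic loess, but were picked for passing, so a shift left by normalization stays open. A candidate explanation is a lower temperature of the loaded leg, and over the 23 rats the leg difference of Rbm3 and Cirbp went against that of the chaperone list (r = -0.470, permutation p = 0.0241, rho = -0.432, permutation p = 0.0409, 1 relation). Without rats 21 and 43 r was -0.164 and rho -0.304, so much of Pearson's r rests on them. In subsets r was -0.472 in date code 3, -0.577 in date code 4, -0.172 at 6 h to 4 d (rho -0.335) and 0.295 at 9 to 14 d (rho 0.371). Temperature cannot be told apart from other effects of loading or from the side of the leg, which stay untested.

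At 9 to 14 d 6 genes of the matrix, gathered because they passed, were higher in the loaded leg at a median of 0.92, while 1 of 16 genes of the fixed matrix list passed, at a median of 0.35, and the matrix protease Mmp11 fell by 0.58. The 13 fibroblast and tendon markers had a median of 0.229 with an SD of 0.47, and 7 of them were above 0, from Fmod at -0.49 to Pi16 at 1.07. The mean over the 6 genes was from 0.290 to 1.51 in the 6 rats, but the genes were picked for passing in these rats, so neither value excludes anything. Without rat 45, 49, 51 or 57 only 2 of the 6 kept their call, and 5 did without rat 47 or 59. More connective tissue in the biopsy, a few rats behind the difference and a response to loading cannot be told apart here.

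Chance was unlikely for the leg difference over 23 rats, with 269 genes against at most 6 in other splits (1 of 100 as large). At 9 to 14 d it was unlikely but not excluded, with 25 against 7 (1 of 32, the smallest share possible). Without rat 49 the count was 6. For duration it was unlikely in each case (1 of 100 splits). At 5 to 8 d and 9 to 14 d counts were 3337 against 27 and 4232 against 757 in unloaded legs. In loaded legs they were 3620 against 3 and 4110 against 1740. These splits ignored the date code, so they do not exclude its effect. Within date code 3 the counts were 16 and 904 in unloaded and 0 and 453 in loaded legs. At 6 h to 4 d (0 against 14) and for the differences between windows in the effect of loading at 9 to 14 d (0 against 1) and 5 to 8 d (0 against 9), limma called 0. All 100 splits are then as large by construction and say nothing about chance. The legs at 5 to 8 d allow 8 splits, too few for a share under 0.05, with 0 real and 45 at most.

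Of 209 groups of 4 to 10 legs, 16 held a leg far from the others; chance flags about 1 in 20 groups, or 10.45 here. In unloaded legs of 5 to 8 d these were Tubb6 in rat 43 at 10.6 (others from 11.8), Sln in rat 55 at 12.2 (others from 13.3) and Psma4 in rat 43 at 9.30 (others from 10.6). In unloaded legs of 9 to 14 d they were, in rat 59, Dclk1 at 9.15 and Myf5 at 9.93, and in rat 51, Ostn at 8.48, Mss51 at 7.57 and Sesn1 at 8.81. In loaded legs of 5 to 8 d Chrna1 was 8.60 in rat 41 (others from 12.6) and Mlf1 6.09 in rat 53. In loaded legs of 9 to 14 d Ankrd1 was 9.93 and Csrp3 8.93 in rat 47 (others from 12.7 and 11.9), Lynx1 6.86 in rat 45, Mymk 11.4 in rat 49, and Mylk2 10.8 and Pfkm 11.9 in rat 59.

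The effect of loading differed between 9 to 14 d and 6 h to 4 d by camera in slow-fibre genes (adjusted p = 5.59e-04, median gap 1.08), matrix proteins (9.69e-04, 0.29), chaperones (0.0026, -0.15), the stretch list (0.0448, 0.14), ribosomal proteins (1.68e-07, -0.12), macrophage markers (0.0414, -0.17) and fibroblast markers (0.0331, 0.24), each with an adjusted p = 0.783 with an estimated correlation. With the legs unblocked the calls of the stretch list (0.0796) and of macrophage and fibroblast markers (0.128 each) ended. Between 5 to 8 d and 6 h to 4 d it differed in slow-fibre genes (0.0035, 1.10), the proteasome (0.0035, 0.10), matrix proteins (0.0222, 0.32), chaperones (0.0222, -0.12), the respiratory chain (0.0203, 0.10), the citric acid cycle (0.0345, 0.11), fatty acid oxidation (5.62e-04, 0.28), calcium release (0.0348, -0.08), ribosomal proteins (2.97e-05, -0.10), the unfolded protein response (5.62e-04, -0.11) and fibroblast markers (0.0345, 0.24), each with an adjusted p = 0.720 with an estimated correlation. With the legs unblocked the calls of the proteasome (0.104), matrix proteins (0.110), the citric acid cycle and calcium release (0.139 each) and fibroblast markers (0.137) ended. Fry called 0 lists in both (smallest adjusted p = 0.360 and 0.655).

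Of 4960 probe sets without a single gene symbol, which no comparison used, 51 passed between the legs of all 23 rats. With duration 1397 passed in unloaded legs at 5 to 8 d and 2207 at 9 to 14 d, and 1521 and 1948 in loaded legs.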

How the results depend on the processing

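Averaging loaded legs 22 and 28 and omitting rats 21 and 27 or 17 and 27 were chosen after seeing the data. The other alternatives were planned.

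Without the rat as a block, which sets the pairing of the legs aside, limma called 3 genes over all 23 rats (269 with it) and 2 at 9 to 14 d (25), and it moved no other count of genes by over 1.5 times. In the 6 comparisons that use the block camera called 45 lists with it and 32 without. Over all comparisons it called 99, and 0 with an estimated correlation. With array quality weights limma called 9 genes between legs at 6 h to 4 d, 1182 at 5 to 8 d, 122 at 9 to 14 d and 876 over all rats, 1 and 526 for the differences between windows (9 to 14 d and 5 to 8 d), and 5375 in unloaded legs at 5 to 8 d. Without a filter on dim probe sets the count over all rats was 163. Within date code 3 limma called 0 between legs at 9 to 14 d (1013 at unadjusted p under 0.05) and 1 over all rats. With duration it called 16 and 904 in unloaded and 0 (1166 unadjusted) and 453 in loaded legs. With the covariate these were 757, 2177, 850 and 1862. The 6 rats of 9 to 14 d alone gave 0 (1206 unadjusted). Averaging legs 22 and 28 gave 2 genes at 6 h to 4 d; leaving out rats 21 and 27 gave 19 there and 438 over all rats, and leaving out rats 17 and 27 gave 1 for the difference between windows at 9 to 14 d. Fewer rats are fitted in the settings that leave rats out; otherwise the cause was not tested.

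Leaving out 1 rat gave 0 to 14 genes at 6 h to 4 d, 0 to 60 at 5 to 8 d, 6 to 92 at 9 to 14 d, 103 to 375 over all rats, and 0 to 3 and 0 to 8 for the differences between windows. With duration it gave 2233 to 3643 and 3639 to 4454 in unloaded legs and 2738 to 3902 and 3614 to 4340 in loaded legs. Of 7703 values of 269 gene results under all alternatives, 7124 kept direction and side of the threshold, 504 lost and 55 gained a call, and 20 turned in sign. Of genes that had passed, these were Psmb4 (-0.11) and C1qc (0.032) in unloaded legs at 5 to 8 d within date code 3, which has 2 and 4 rats. The other 18 passed neither before nor after. Over all rats Myh7 turned with array quality weights (0.19), within date code 3 (0.18), with equal weight for each window (0.30), without rats 21 and 27 (0.11) or 17 and 27 (0.18), and without 1 rat in 4 cases (-0.37 to 0.069 over all), and Mstn turned without rats 17 and 27 (-0.0062). Myh7 turned at 6 h to 4 d within date code 3 (0.24). Between the legs at 5 to 8 d Fbxo32 turned with array quality weights (-0.068) and without rat 43 (-0.020 to 0.17 with 1 rat left out). In unloaded legs at 5 to 8 d Fbxo32 and Trim63 turned within date code 3 (-0.33 and -0.78) and with the date code as a covariate (-0.11 and -0.62), and Trim63 without rat 55 (-0.0014 to 0.91 with 1 rat left out). The cause was not tested.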

Other observations

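The lists and tests in this part were fixed beforehand, and the choice to give these values was made after the result was seen.

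Some lists moved in part without being called by camera. Of 16 unfolded protein and ATF4 genes 7 passed higher in unloaded legs at 5 to 8 d and 9 did not pass, 7 higher and 1 lower adjusted over the list alone, at a median of 0.31 (camera adjusted p = 0.138). With the date code as a covariate 2 passed higher, at a median of 0.13, and after cyclic loess 7 were higher and 3 lower, at 0.23. Of 20 autophagy and lysosome genes 7 passed higher, 1 lower and 12 did not in loaded legs at 5 to 8 d, 9 and 1 adjusted over the list alone, at a median of 0.26 (camera adjusted p = 0.0832). With the covariate 4 were higher and 1 lower, at a median of 0.19, and after cyclic loess 4 and 2, at 0.13. Of 17 stretch and Z-disc genes 8 passed higher and 2 lower in loaded legs at 5 to 8 d, 8 and 4 adjusted over the list alone; the median was 0.45 and camera's direction was down (adjusted p = 0.986). With the covariate 1 was higher and 2 lower, at a median of 0.23, or 0.13 within date code 3, and after cyclic loess 3 were higher and 4 lower, at 0.30. At 9 to 14 d 8 were higher and 2 lower, the same adjusted over the list alone, at a median of 0.37 (camera adjusted p = 0.588). With the covariate 3 were higher and 2 lower, at a median of 0.46, and after cyclic loess 5 and 3, at 0.31.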
